A study of Homo sapiens with 54 samples.

How the data were processed

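RNA sequencing libraries from BT549 cells, a line established from a human triple-negative breast tumour with a mesenchymal appearance, were compared in 3 experiments. The 54 libraries fall into 18 groups of 3, and every library could be placed in a group from its label. In the GATA6 experiment, cells received a control siRNA (siCtl) or a pool of siRNAs against the transcription factor GATA6 (siGATA6) for 72 h and then vehicle or 500 nM dexamethasone (DEX), a synthetic glucocorticoid that activates the glucocorticoid receptor, for 2 h. In the BRM014 experiment, cells received DMSO or 10 µM BRM014, an inhibitor of the ATPases of the SWI/SNF chromatin remodelling complex (BRG1, encoded by SMARCA4, and BRM, encoded by SMARCA2), with or without 500 nM DEX, for 4 h or 24 h. The 24 h time is that of the sample labels, whereas the treatment protocol in the labels names 2 h or 4 h for DEX and 4 h for BRM014, and the BRM014 dose comes from that protocol. In the AP-1 experiment, cells received siCtl, siRNA against FRA1 (encoded by FOSL1) or siRNA against JUN, with vehicle or DEX. The labels of that experiment do not state how long DEX was given. There the library number in the header of each table differs from the number under which it was deposited, and each table was taken as that of the sample it was deposited for. MDA-MB-231 cells, which the series' design also names, were not analysed here.

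Per the labels' protocols, RNA was extracted with Tri-reagent, ribosomal RNA was depleted, NEBNext libraries were made and paired ends were read on a NovaSeq instrument. The labels give the molecule as total RNA in the GATA6 and BRM014 experiments and as polyA RNA in the AP-1 experiment, although the shared protocol describes depletion of ribosomal RNA for all. The non-polyadenylated RN7SK had medians of 4.75, 1.25 and 96.2 CPM in the GATA6, BRM014 and AP-1 experiments, so levels were never compared across experiments. The values are raw read counts per gene, which the authors deposited as 1 table per library with 26517 gene symbols. Per the submitters' processing notes, bcl2fastq, SAMtools, featureCounts and DESeq2 were used with builds GRCh38 and hg38, and per the file headers of the AP-1 experiment the counts were made from primary STAR alignments. Their versions, the gene annotation, the strand setting and, for the other experiments, the aligner are not given in the sources used here. Genes that overlap an antisense partner or share reads with a near-identical copy (HSPA1A and HSPA1B, SLC2A3 and SLC2A14, the MT1 and histone genes, RNA45S5) are therefore uncertain. A further table equal to that of an AP-1 control library (1 table) was not used. Coordinates are from the reference annotation of GRCh38.

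Total counts per library ranged from 12888724 to 30530736 in the GATA6, 13243316 to 29339329 in the BRM014 and 10186607 to 16352524 in the AP-1 experiment. No pair of replicates was a repeat of the same library: over 54 pairs the chi-square of counts per degree of freedom lay between 3.04 and 106. The labels number biological replicates in the GATA6 and BRM014 experiments, and replicates of no stated kind in the AP-1 experiment. No label says how they were made, so p-values measure the spread between these samples, which in the AP-1 experiment may be technical.

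Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with a mean for each group and no other covariate. Genes were filtered with filterByExpr, which left 13897, 14547 and 13658 genes in the GATA6, BRM014 and AP-1 experiments. Counts were scaled by TMM factors, dispersions were estimated, and each comparison was tested with edgeR's quasi-likelihood test (robust), two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. All adjusted p-values of genes come from this test unless another tool is named. The biological coefficient of variation was 5.57%, 18.8% and 9.8%. CPM, counts scaled to a fixed library total, were computed with TMM-scaled totals and are given as mean and SD over 3 libraries. Log2 fold changes (log2FC) carry their standard error (SE). For genes with 3 or fewer counts over the 3 libraries of a group, the ratio of summed CPM is given with its 0.95 exact interval, and for a group at 0 counts a lower bound is given against a floor of 3 counts over the group. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

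The choice of groups, tests, thresholds, named genes, gene lists and most alternatives was made before the data were examined. GATA6, FOSL1, JUN, SMARCA4, SMARCA2 and the glucocorticoid receptor gene NR3C1 were followed in every group. For each main effect, the 10 called genes with the largest rise and the 10 with the largest fall are named if their mean was at least 5 CPM in the higher group and the replicates of the groups did not overlap. For interactions and differences between times or siRNAs, 5 and 5 are named without the overlap condition. Some genes that these rules take are not reported here. Symbols of unnamed loci, long non-coding, antisense and small RNAs were left out. The 19 fixed lists hold genes often induced by glucocorticoids, cytokine genes often repressed by them, SWI/SNF subunits, AP-1 family members, YAP/TEAD targets, mesenchymal, epithelial, luminal breast and leukocyte genes, proteases and their inhibitors, TGF-beta and BMP response, cell cycle, interferon response, cholesterol synthesis, integrated stress and unfolded protein response, heat shock, immediate early, p53 target and core histone genes. From each list the called members with the largest change are cited. Lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Of 119 calls made in this way, 16 held with the correlation estimated from the data. Sets of genes induced, or repressed, by DEX in the control cells of both other experiments were tested in each interaction with fry (10 tests), which asks whether a set's genes move on balance 1 way. Overlaps of BRM014 calls with siRNA calls were tested with Fisher's exact test (24 tests), in genes tested in both experiments.

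Same-numbered libraries deviated together from their group means in the GATA6 experiment (18 of 18 correlations between groups above 0.1, from 0.205 to 0.606) and in the AP-1 experiment (45 of 45, from 0.131 to 0.643). In the BRM014 experiment they did so for DEX at 4 h and 24 h in DMSO and for DEX at 24 h in BRM014 (3 of 3 in each, from 0.29 to 0.966). That experiment was first taken as not paired, and this was decided per comparison after the blocked calls had been seen. In these comparisons the replicate numbers pair the libraries, as read from the data and not from the labels, and the fit with replicate number as a block is given beside a result where it changes a call or moves a count by over 1.5 times.

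The procedure was tested on simulated counts with the real means, library sizes and dispersions, in which 200 genes were changed 1.5-fold or 2-fold. For DEX at 2 h 94% of the genes changed 1.5-fold and 98% of those changed 2-fold were called. For the siGATA6 by DEX interaction the shares were 84% and 97%, and for BRM014 at 4 h 51% and 81%. For the BRM014 by DEX interaction at 4 h they were 7% and 46%, and for siFRA1 73% and 92%. For siFRA1 by DEX they were 44% and 89%. A simulated GC trend gave 77 to 5583 false calls, and 1 to 13 once removed. The other interactions of the BRM014 experiment were not simulated.

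Alternatives were RLE scaling, library totals alone, no filter on low counts, a mean of at least 1 CPM, the replicate block, fits of a comparison's own groups, DESeq2 1.42.0, leaving out each replicate in turn, stricter or other gene sets and estimated camera correlations. After the data were seen, removal of each library's trend with transcript GC content (lowess, span 0.3, as offsets), alone or with the block, estimated correlations with the block and omission of the 8 replicate-2 libraries of the BRM014 experiment were added. The slope of log2 CPM on GC fraction (GC slope) ran from -0.389 to 0.444 in the GATA6, -1.01 to 0.536 in the AP-1 and -2.22 to 4.4 in the BRM014 experiment. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.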

Results

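The data are RNA sequencing counts from BT549 breast cancer cells in 54 libraries, 18 groups of 3. The GATA6 experiment had 12 libraries in 4 groups. That with the SWI/SNF inhibitor BRM014 had 24 in 8, and the AP-1 experiment 18 in 6. Levels below are means ± SD over the 3 libraries of a group in CPM, counts scaled to the library total. Genes named for the size of their change had a mean of at least 5 CPM in the higher group and, for main effects, no overlap between the replicates of the groups.

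The genes targeted by siRNA were read first, since they check the labels. GATA6, a zinc-finger transcription factor gene (protein-coding, chromosome 18, 22169589 to 22202528, GRCh38), was at 85.3 ± 6.51 CPM in siCtl with vehicle and at 10.3 ± 0.164 CPM in siGATA6 with vehicle (log2FC -3.04, SE 0.0681, adjusted p = 9.37e-19). With DEX it was at 116.5 ± 2.78 and 16.6 ± 1.24 CPM. FOSL1, which encodes the AP-1 subunit FRA1 (chromosome 11, 65892049 to 65900545), was at 172.1 ± 11.6 CPM in siCtl and 46.8 ± 5.22 CPM in siFRA1 with vehicle (log2FC -1.88, SE 0.181, adjusted p = 1.21e-05), and at 60.1 ± 8.66 and 12.8 ± 1.75 CPM with DEX. JUN, which encodes another AP-1 subunit (chromosome 1, 58780791 to 58784047), was at 280.4 ± 12.02 CPM in siCtl and 99.1 ± 13.1 CPM in siJUN with vehicle (log2FC -1.50, SE 0.213, adjusted p = 9.31e-04), and at 64.6 ± 21.2 CPM in siJUN with DEX. The genes of the ATPases that BRM014 inhibits, SMARCA4 (chromosome 19, 10961030 to 11062273) and SMARCA2 (chromosome 9, 2015347 to 2193620), passed the threshold in a single comparison: SMARCA2 was higher in siJUN than in siFRA1 cells (log2FC 0.42, SE 0.12, adjusted p = 0.0331).

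**Figure D1:**
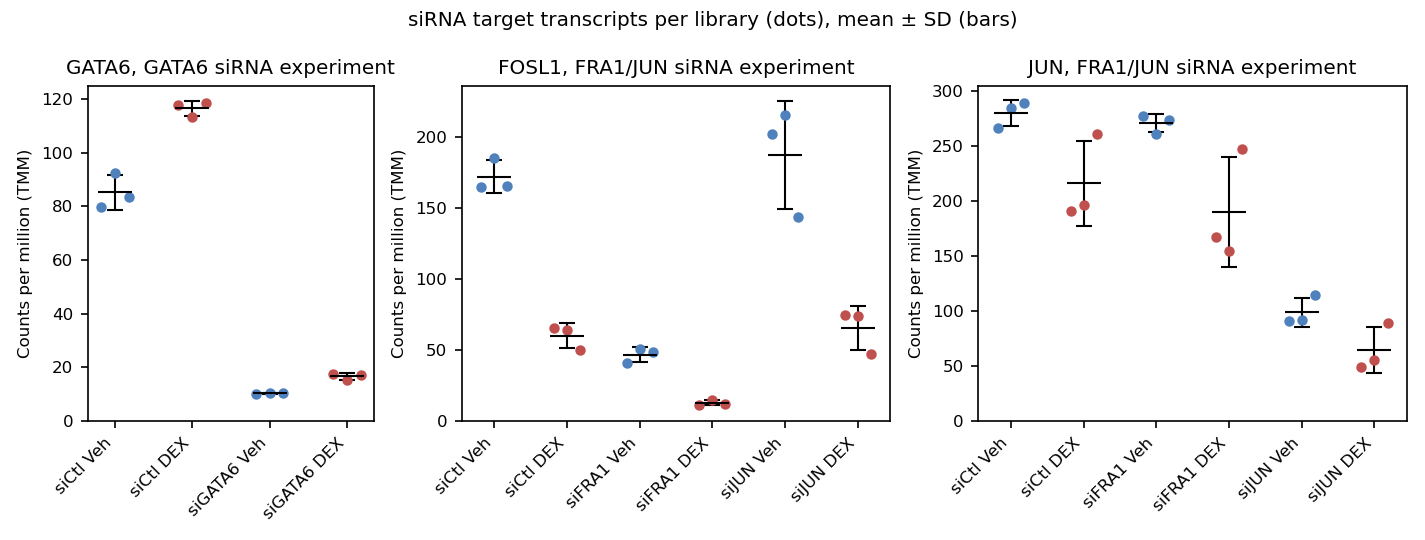
Levels of GATA6, FOSL1 and JUN in CPM in each library (dots), with the mean and SD of each group of 3, in the siRNA experiments. Each gene is lower in the groups that received its siRNA, such as GATA6 at 10.3 CPM in siGATA6 against 85.3 CPM in siCtl with vehicle.

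Which genes respond to glucocorticoid within 2 h was asked by comparing DEX with vehicle in siCtl cells of the GATA6 experiment. PDK4, whose product inhibits pyruvate dehydrogenase, rose from 0.241 ± 0.202 to 111.5 ± 9.01 CPM (n = 3 each), a 491-fold rise (log2FC 8.94, SE 0.145, adjusted p = 4.38e-22). TSC22D3, which encodes the anti-inflammatory protein GILZ (chromosome X, 107713221 to 107775988), rose 47.8-fold to 156.6 ± 8.27 CPM. The other large rises were 38.2-fold for RASD1, 37.6-fold for F3 (tissue factor), 30.3-fold for FKBP5, which encodes a receptor co-chaperone (chromosome 6, 35573590 to 35728583), and 11.2-fold for the transcription factor gene KLF9. OSR1 (log2FC 4.17), SERPINA3 (3.61), ITPKA (3.59) and the thiamine transporter gene SLC19A2 (3.57) completed the 10 largest. ZBTB16, a further receptor target (chromosome 11, 114059711 to 114256770), went from 2 counts over the vehicle group to 109, a ratio of 59.2 (counting interval 16 to 495).

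The largest falls at 2 h were in SOWAHD (28.4 ± 1.66 to 3.35 ± 0.719 CPM, 8.54-fold lower, adjusted p = 4.30e-08) and in IER3, an early response gene that was 7.37-fold lower. PCDH18 (6.22-fold lower), CXCL8, which encodes interleukin 8 (38.5 ± 1.19 to 6.74 ± 0.683 CPM, 5.74-fold lower) and TNFSF9 (5.24-fold) also fell. GDF15 (5.08-fold), PDE4B (4.93-fold), LURAP1L (4.72-fold) and LIF (4.63-fold) were lower too. FOSL1 itself fell by 1.82 on the log2 scale (SE 0.105, adjusted p = 6.61e-08) and the receptor gene NR3C1 (chromosome 5, 143277931 to 143435512) fell by 0.41 (SE 0.0475, adjusted p = 7.44e-07).

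Of 27 tested genes often induced by glucocorticoids, 24 rose and 1 fell (25 and 1 adjusted over the list alone), with a median log2FC of 1.66 (camera adjusted p = 2.44e-130, and adjusted p = 5.11e-05 with an estimated correlation). Of 10 tested cytokine genes often repressed by them, 4 fell (1 rose and 6 fell adjusted over the list alone), CXCL8, LIF, CXCL3 and ICAM1 (camera adjusted p = 0.00191, and adjusted p = 0.418 with an estimated correlation). In the AP-1 family 7 of 16 fell and 2 rose, also adjusted over the list alone, with FOSL1, MAF (-1.52) and ATF3 (-0.89) lowest (camera adjusted p = 0.00995, and adjusted p = 0.399 with an estimated correlation). TGF-beta and BMP response genes included falls in SMAD6 (-2.06), ID3 (-1.72) and SMAD7 (-1.29), 5 lower and 2 higher of 15 (5 and 3 adjusted over the list alone; camera adjusted p = 8.23e-05, and adjusted p = 0.254 with an estimated correlation). Of 24 cholesterol synthesis and uptake genes 9 fell (13 adjusted over the list alone), HMGCS1 (-0.61) among them (camera adjusted p = 4.00e-05, and adjusted p = 0.418 with an estimated correlation). YAP/TEAD readout genes were called higher with F3 and GADD45A in the lead, 5 higher and 3 lower of 21 (5 and 4 adjusted over the list alone; adjusted p = 5.65e-04, and adjusted p = 0.366 with an estimated correlation). The mesenchymal list was also called higher (0.00191, and adjusted p = 0.418 with an estimated correlation) on 3 of 24 members, ZEB2 (1.74), TWIST1 (1.29) and PRRX1 (1.02), the same count adjusted over the list alone. Its mean was 0.16, but its median was 0.00, and -0.04 with library totals alone. Interferon response genes had 1 of 30 lower, IRF1, also adjusted over the list alone, and a median of -0.14 (adjusted p = 0.105, and adjusted p = 0.828 with an estimated correlation). With replicate number as a block the list was called lower (0.00222, and adjusted p = 0.595 with an estimated correlation). Their median was 0.05 without siCtl vehicle replicate 3 and 0.08 without siCtl DEX replicate 2, and at the preset correlation the list was called without siCtl vehicle replicate 2 (0.0404) or siCtl DEX replicate 3 (0.00894).

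In all, 1215 genes were higher and 1001 lower at 2 h (270 and 121 by at least 2-fold). Library totals alone gave 972 higher and 1476 lower.

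In siGATA6 cells, 1109 genes were higher and 1106 lower after 2 h of DEX (367 by at least 2-fold, 119 of them lower), against 949 and 1488 with library totals alone. PDK4 (311-fold, 95.1 ± 2.58 CPM with DEX), TSC22D3 (88.0-fold), OSR1 (25.4-fold), RASD1 (24.5-fold), FKBP5 (23.3-fold), F3 (20.5-fold), KLF9 (14.4-fold) and SLC19A2 (12.8-fold) again rose most. MT1M, a metallothionein gene with near-identical relatives (log2FC 3.57), and ADAMTS8 (3.55) were also among the 10. The falls included SOWAHD (7.46-fold), IER3, PDE4B, CXCL8 (5.29-fold), TNFSF9, TNFSF15 (log2FC -2.33), BCL3 (-2.09), FAM46C (-2.09) and PLK2 (-2.02). Of the cytokine list 8 of 10 fell (1 rose and 8 fell adjusted over the list alone; camera adjusted p = 2.37e-04, and adjusted p = 0.319 with an estimated correlation), now with PTGS2 (-1.40) and CCL2 (-1.07). JUN fell by 0.49 here (adjusted p = 5.78e-08), while in siCtl its log2FC was -0.02 (adjusted p = 0.863).

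What siGATA6 does without hormone was read from siGATA6 against siCtl with vehicle. MOSPD1 (129.0 ± 13.3 to 29.2 ± 2.92 CPM, 4.43-fold lower) and the endoplasmic reticulum stress sensor gene ATF6B (113.4 ± 5.59 to 27.4 ± 0.738 CPM, 4.13-fold lower) were, beside GATA6 itself, the largest falls within these limits. DKK1, which encodes a secreted Wnt inhibitor, fell from 105.1 ± 4.34 to 30.2 ± 1.06 CPM (log2FC -1.80, SE 0.059, adjusted p = 1.17e-15). PDK1 (-1.79), LUZP2 (-1.74), GPR1 (-1.64), PTPRD (-1.60) and KLHL4 (-1.50) were also lower. The homeobox gene MSX1 rose 3.28-fold (6.58 ± 0.428 to 21.3 ± 1.68 CPM, adjusted p = 1.34e-10), followed by PLXDC1 (2.99-fold), CD274, which encodes the immune checkpoint ligand PD-L1 (2.82-fold), SH3TC2, ANKRD33B (29.3 ± 1.23 to 82.7 ± 2.83 CPM), FGF1 (2.69-fold), the apoptosis inhibitor gene BIRC3 (2.64-fold), THSD1 and HERC3. FOSL1 rose by a log2FC of 0.72 (SE 0.0932, adjusted p = 1.69e-04) and JUN by 0.36.

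In all, 1676 genes were higher and 1615 lower, 97 and 96 of them by at least 2-fold. Of 20 immediate early genes 10 rose, with none lower (13 adjusted over the list alone), KLF2 (0.97), IER5 (0.87) and ARC (0.82) first (camera adjusted p = 1.94e-05, and adjusted p = 0.404 with an estimated correlation). YAP/TEAD readout genes showed 13 of 21 higher and 2 lower, also adjusted over the list alone, with FOXF2 (2.32) and NUAK2 (0.81) in the lead (camera adjusted p = 2.57e-05, and adjusted p = 0.404 with an estimated correlation). The AP-1 list was called higher with 5 up and 2 down of 16 (9 and 2 adjusted over the list alone; adjusted p = 0.024, and adjusted p = 0.488 with an estimated correlation), with a median of 0.25 but a mean of -0.01, since MAF fell by 3.63. Of 18 stress response genes 9 were lower, also adjusted over the list alone, such as ERN1 (-0.86) and DDIT4 (-0.53) (adjusted p = 2.57e-05, and adjusted p = 0.404 with an estimated correlation). Of 24 cholesterol genes 11 fell and 1 rose (11 and 2 adjusted over the list alone; adjusted p = 1.22e-04, and adjusted p = 0.537 with an estimated correlation). Genes often induced by glucocorticoids rose in 10 and fell in 2 of 27 (10 and 3 adjusted over the list alone; adjusted p = 0.00723, and adjusted p = 0.488 with an estimated correlation), although TSC22D3 (-1.40) and KLF9 (-0.55) were lower. KRT19 (-2.48) and KRT8 (-1.01) fell, but the epithelial list had a median of 0.26 and was not called (adjusted p = 0.921). Interferon response genes had a median of 0.27 with 1 of 30 called, IRF1 (1 adjusted over the list alone; adjusted p = 0.358). With replicate number as a block the list was called (2.39e-04, and adjusted p = 0.606 with an estimated correlation). With that block the mesenchymal list was called lower as well (0.0158, against 0.327 without it, and adjusted p = 0.302 with an estimated correlation), its median being -0.06 with falls in COL3A1 (-0.92) and POSTN (-0.54). The siGATA6 libraries also held more of the non-polyadenylated RN7SK (8.52 ± 2.98 against 3.02 ± 0.409 CPM) and of the ribosomal precursor RNA45S5 (35.7 ± 13.5 against 11.5 ± 0.592 CPM, log2FC 1.61, adjusted p = 0.00961).

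Whether siGATA6 alters the DEX response was tested as an interaction. DKK1 showed the largest gain: DEX took it from 30.2 ± 1.06 to 102.8 ± 6.83 CPM in siGATA6 and from 105.1 ± 4.34 to 136.9 ± 8.23 CPM in siCtl (interaction 1.38, SE 0.0796, adjusted p = 4.38e-10). TSC22D3 (0.88), the phosphatase gene DUSP5 (0.72), S1PR3 (0.71) and PCDH18 (0.66) also had a higher DEX ratio in siGATA6. C10orf10 had a lower one (-1.19, adjusted p = 5.48e-04), at 25.6 and 7.29 CPM without and with DEX in siGATA6 against 33.0 and 21.1 CPM in siCtl. MSX1 (-0.93), BIRC3 (-0.93), IL6 (-0.80) and GPR37 (-0.80) followed, and JUN was called too (-0.47, SE 0.0685, adjusted p = 0.00108). In total 13 genes were higher and 34 lower, and 30 in total without siGATA6 DEX replicate 2. The replicate block gave 90 higher and 162 lower, DESeq2 88 in total, and the log2 interaction rose with transcript GC content (Spearman rho 0.51 across genes, which are not independent). No list was called, but with the block interferon (4.64e-04) and stress genes (0.0342) were, their medians in that fit being 0.09 and 0.05. Neither held with an estimated correlation (adjusted p = 0.642 for each). The 361 genes induced by DEX in control cells of both other experiments had a median interaction of -0.05 (fry adjusted p = 0.0706, and 0.0462 with the block), with 16 called smaller and 4 larger. The 171 repressed ones had a median of 0.03 (fry adjusted p = 0.436).

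Longer exposure to DEX was measured in DMSO cells of the BRM014 experiment, where 4 h was compared with DMSO at 4 h and 24 h with DMSO at 24 h. At 4 h FKBP5 rose 174-fold, from 0.982 ± 0.257 to 169.2 ± 9.12 CPM (log2FC 7.44, SE 0.274, adjusted p = 1.35e-13), PDK4 553.2-fold to 179.7 ± 9.71 CPM and TSC22D3 89.4-fold. Several genes started at or near 0 counts: ALOX15B, a lipoxygenase gene, rose at least 121-fold, and the ratios were 779 for ZBTB16 (interval 139 to 30800), 572 for SLC6A19 (102 to 22600), 247 for EDN2 (84.3 to 1200), 242 for FGD4 (66.6 to 2000), 211 for KLF15 (71.9 to 1030) and 201 for SLC2A14 (55.4 to 1670), which shares reads with SLC2A3. SOWAHD (11.6-fold lower), TNFSF15 (11.5-fold), LIF (11.2-fold), PCDH18 (9.18-fold), CXCL8 (29.4 ± 11.3 to 3.64 ± 1.37 CPM), EYA1 (7.41-fold), IER3, PLK2 and TMEM217 were among the largest falls, and FOSL1 fell by 1.97. In all, 1130 genes were higher and 695 lower (533 and 215 by at least 2-fold). Library totals alone gave 960 and 1049, the fit of these groups alone 2868 in total, and the fit without the replicate-2 libraries, with fewer samples, 1065.

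Of the glucocorticoid-induced list 24 of 27 rose at 4 h (25 adjusted over the list alone; median 1.99, camera adjusted p = 9.15e-117, and adjusted p = 3.44e-09 with an estimated correlation). Of the cytokine list 6 of 11 fell, also adjusted over the list alone (adjusted p = 2.17e-06, and adjusted p = 0.27 with an estimated correlation). FOS (2.36) and ZFP36 (1.91) rose and DUSP6 (-1.49) fell within the immediate early list, 8 up and 5 down of 20 (9 and 6 adjusted over the list alone), which was not called (adjusted p = 0.513). Interferon response genes had 2 of 30 lower, IFIT2 (-1.96) and IRF1 (-1.13), also adjusted over the list alone, and a median of -0.22 (adjusted p = 0.0892). With replicate number as a block the list was called lower (4.92e-05, and adjusted p = 0.3 with an estimated correlation).

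At 24 h FKBP5 had risen 1144-fold, to 1344 ± 63.8 CPM from 1.18 ± 0.138 CPM (adjusted p = 9.41e-15). CXCL13, a chemokine gene, went from 2 to 3874 counts over the group (ratio 2660, interval 736 to 22000) and ZBTB16 from 3 to 3011 (1380, 471 to 6690). CIDEC, a lipid droplet gene (567, 101 to 22500), ALOX15B (301, 82.8 to 2490), ABLIM3 (log2FC 8.60), TFCP2L1 (8.15), HIF3A (7.78), PDK4 (7.71) and LBH (7.70) completed the 10. Of 30 interferon response genes 24 fell (28 adjusted over the list alone) with a median of -2.16. MX1, an antiviral GTPase gene, went from 646 ± 240 to 44.2 ± 30.1 CPM (log2FC -3.87, SE 0.645, adjusted p = 2.35e-04), RSAD2 fell by 4.70 and IFIT1 by 4.00 (camera adjusted p = 1.79e-15, and adjusted p = 0.204 with an estimated correlation). Other large falls were in RSPO3 (-4.82), GBP4 (-4.60), SEMA5B (-4.57), CPA4 (-4.52), NDP (-4.36), IDO1, which encodes a tryptophan-degrading enzyme (-4.23), and VAV3 (-3.86). MMP7 was at 0 counts in DMSO and rose at least 118-fold.

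Of 18 epithelial genes 11 were lower at 24 h, also adjusted over the list alone (median -0.90, camera adjusted p = 3.60e-05, and adjusted p = 0.167 with an estimated correlation), such as MAL2 (-2.96) and KRT19 (-2.51), with GRHL2 at 28 counts in DMSO and 3 with DEX (6.80-fold, interval 2.10 to 34.9). Luminal breast genes fell in 5 of 7, also adjusted over the list alone, KRT18 (-1.90) and KRT8 (-1.03) first (adjusted p = 0.0129, and adjusted p = 0.138 with an estimated correlation). In the cytokine list 10 of 11 fell (10 and 1 higher adjusted over the list alone), PTGS2 by 4.02 (adjusted p = 1.31e-05, and adjusted p = 0.167 with an estimated correlation). Protease and inhibitor genes had 11 of 21 lower and 2 higher (12 and 3 adjusted over the list alone; adjusted p = 7.26e-04, and adjusted p = 0.293 with an estimated correlation). Stress response genes had 11 of 18 lower and 1 higher, DDIT4 (13 and 1 adjusted over the list alone; 0.00229, and adjusted p = 0.293 with an estimated correlation). TGF-beta and BMP genes had 8 of 15 lower and 4 higher, also adjusted over the list alone (0.0486, and adjusted p = 0.167 with an estimated correlation). Cell cycle genes rose in 12 of 32 (16 adjusted over the list alone), CDT1 (0.61) and CCNE1 (0.52) first (0.00784, and adjusted p = 0.515 with an estimated correlation). Of the glucocorticoid-induced list 20 rose and 1 fell, also adjusted over the list alone (adjusted p = 9.61e-73, and adjusted p = 9.46e-08 with an estimated correlation). JUN fell by 0.64 and GATA6 by 0.67 (adjusted p = 4.86e-04). In all, 1827 genes were higher and 1890 lower, against 1788 in total with these groups alone and 1945 without the replicate-2 libraries.

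**Figure D2:**
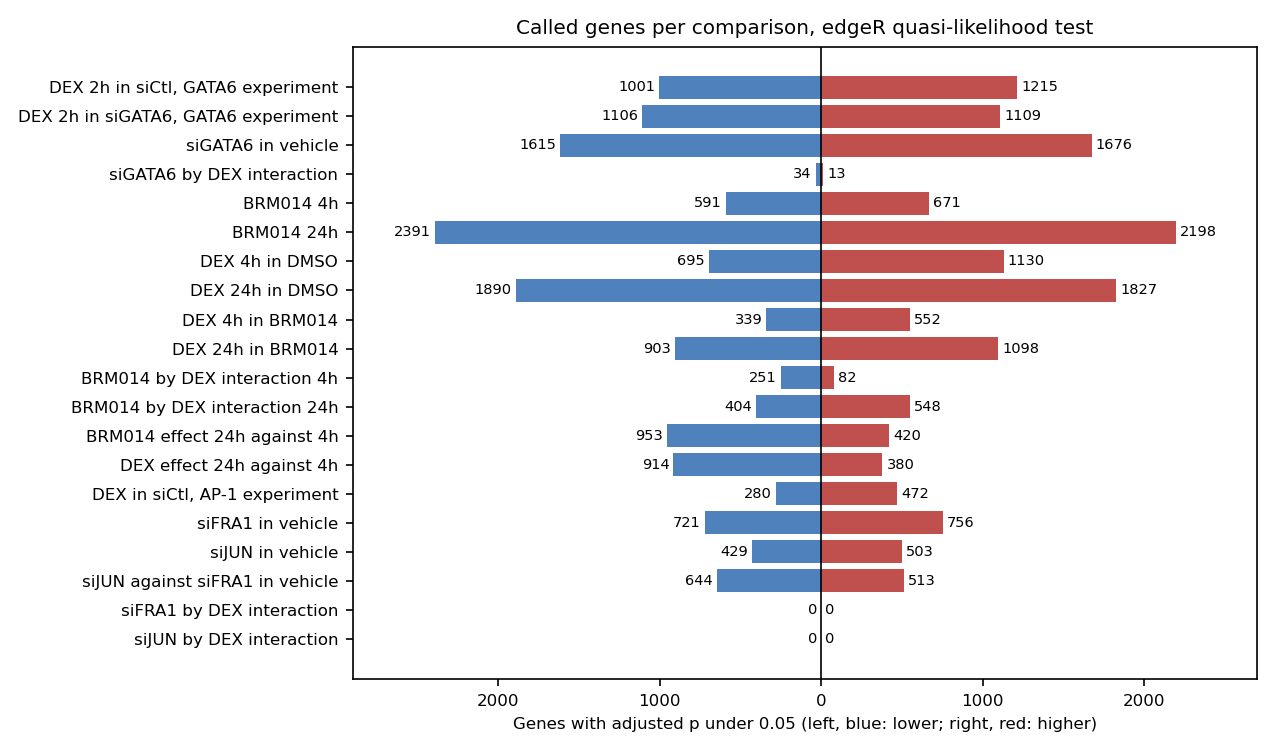
Number of genes higher (above 0) and lower (below 0) at an adjusted p under 0.05 in each comparison, from edgeR's quasi-likelihood test on 3 libraries per group. BRM014 at 24 h has 4589 genes and DEX at 24 h 3717, the latter being 1788 with these groups alone and 1945 without the replicate-2 libraries, and the siFRA1 and siJUN interactions with DEX have 0.

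The effect of the ATPase inhibitor alone was read from BRM014 against DMSO. At 4 h C10orf10 fell from 21.3 ± 2.65 to 1.70 ± 0.491 CPM (12.3-fold, log2FC -3.62, SE 0.324, adjusted p = 5.43e-07) and ELF3, an epithelial transcription factor gene, from 11.8 ± 1.97 to 1.22 ± 0.288 CPM. BLACAT1 (8.09-fold lower), TXNIP, which encodes a glucose uptake regulator (7.79-fold), GDF15 (5.78-fold), C2CD4A (log2FC -2.38), FGF18 (4.54-fold), the bradykinin receptor gene BDKRB2 (4.08-fold), LRRC32 (3.99-fold) and CSF1 (150.1 ± 7.81 to 37.3 ± 3.20 CPM) also fell. The nuclear receptor gene NR4A2 rose 3.48-fold (adjusted p = 0.00179), followed by CXCL3 (3.23-fold), KCNJ2, C8orf37, BACH2 (2.88-fold), ZNF775, SGK223, BSN and FAM124A. FOSL1 fell by 1.60 (42.6 to 14.1 CPM, SE 0.189, adjusted p = 1.18e-05) and JUN by 0.46 (adjusted p = 0.0429).

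Of 14 heat shock genes 5 fell at 4 h (6 adjusted over the list alone), the paralogs HSPA1B (-1.24) and HSPA1A (-1.03) and DNAJB1 (-0.61) among them (median -0.34, camera adjusted p = 2.72e-08, and adjusted p = 1.68e-04 with an estimated correlation). Protease and inhibitor genes had 5 of 21 lower and 1 higher, also adjusted over the list alone, PLAU (-1.27) and TIMP3 (-0.89) among them (adjusted p = 0.00934, and adjusted p = 0.632 with an estimated correlation). Of 18 p53 target genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; 0.0358, and adjusted p = 0.281 with an estimated correlation), and of 18 epithelial genes ELF3 alone was called, also adjusted over the list alone (0.0358, and adjusted p = 0.658 with an estimated correlation). Immediate early genes were called higher, 5 up and 1 down of 20 (6 and 2 adjusted over the list alone; 0.0264, and adjusted p = 0.658 with an estimated correlation), and cell cycle genes lower, 5 of 32, also adjusted over the list alone (0.0358, and adjusted p = 0.736 with an estimated correlation). Neither of these lists was called once each library's GC trend was removed, with adjusted p = 0.0879 for immediate early genes. SWI/SNF subunit genes had 4 of 27 higher and 2 lower, also adjusted over the list alone, GLTSCR1L (1.14) and DPF3 (-1.02) first (adjusted p = 0.252).

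In all, 671 genes were higher and 591 lower at 4 h (77 and 156 by at least 2-fold). The fold changes rose with transcript GC content (rho 0.45 across genes). The GC slope was 2.01 in BRM014 4 h replicate 3 and -1.24 to -0.518 in the other libraries compared. The count was 832 without BRM014 4 h replicate 3, 751 and 812 without DMSO 4 h replicate 1 or 3, and 383 (158 higher, 225 lower) without the replicate-2 libraries, with fewer samples.

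At 24 h the response was larger. ELF3 was 53.7-fold lower (12.8 ± 6.25 to 0.229 ± 0.137 CPM, adjusted p = 5.42e-08). GBP2 (33.3-fold lower), TXNIP (32.8-fold), KCNK3 (30.4-fold), KRT19 (27.9-fold), LRRC32 (25.9-fold), KLHDC7B (25.1-fold, from 10.1 ± 10.6 CPM) and SLC12A8 (22.3-fold) also fell. The rises were led by C2CD4C (9.63-fold), the neuronal kinesin gene KIF1A (8.28-fold), FGFR3 (4.54 ± 0.394 to 37.4 ± 3.07 CPM, log2FC 3.04, SE 0.159, adjusted p = 2.67e-11), CHD5 (7.17-fold), TMEM145, TMEM151A, C8orf37, APC2, EEF1A2 and the synaptic vesicle gene SYP (5.11-fold). FOSL1 (-1.94, adjusted p = 1.21e-07) and JUN (-0.93, adjusted p = 2.69e-05) were lower.

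Interferon response genes fell in 24 of 30 (25 adjusted over the list alone), with RSAD2 (-3.86) and IFI44L (-3.83) lowest (median -1.62, camera adjusted p = 2.11e-07, and adjusted p = 0.346 with an estimated correlation). The cytokine list fell in 10 of 11, also adjusted over the list alone, with CXCL8 (-3.26) and IL6 (-2.78), and CCL20 was at least 6.16-fold lower (adjusted p = 2.72e-07, and adjusted p = 0.0959 with an estimated correlation). Mesenchymal genes had 12 of 24 lower and 2 higher, also adjusted over the list alone, such as S100A4 (-2.29), SPARC (-2.06) and COL1A2 (-1.77) (2.11e-07, and adjusted p = 0.0605 with an estimated correlation). Epithelial genes fell too, 9 of 18 (9 and 1 higher adjusted over the list alone), KRT7 (-2.51) and PKP3 (-1.83) beside ELF3 and KRT19 (1.53e-06, and adjusted p = 0.0959 with an estimated correlation). Protease and inhibitor genes had 14 of 21 lower and 1 higher (15 and 1 adjusted over the list alone), with TIMP3 (-3.07) and MMP1 (-1.48) (6.17e-08, and adjusted p = 0.0959 with an estimated correlation). YAP/TEAD readout genes had 12 of 21 lower and 3 higher, also adjusted over the list alone (0.0126, and adjusted p = 0.136 with an estimated correlation), with F3 at a ratio of 4.62 (interval 1.31 to 24.9) lower. AP-1 family genes had 7 of 15 lower (7 and 1 higher adjusted over the list alone; 0.00792, and adjusted p = 0.346 with an estimated correlation), cholesterol genes 10 of 24 (12; 7.22e-04, and adjusted p = 0.346 with an estimated correlation), heat shock genes 8 of 14 (9; 0.00806, and adjusted p = 0.0701 with an estimated correlation), and glucocorticoid-induced genes 9 of 27 with 1 higher (12 and 3; 0.0367, and adjusted p = 0.346 with an estimated correlation), the values in brackets being those adjusted over the list alone. In all, 2198 genes were higher and 2391 lower (609 and 919 by at least 2-fold). With library totals alone the split was 3672 and 1785, since the median of all genes then shifted by 0.135, and without the replicate-2 libraries the total was 3036.

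**Figure D3:**
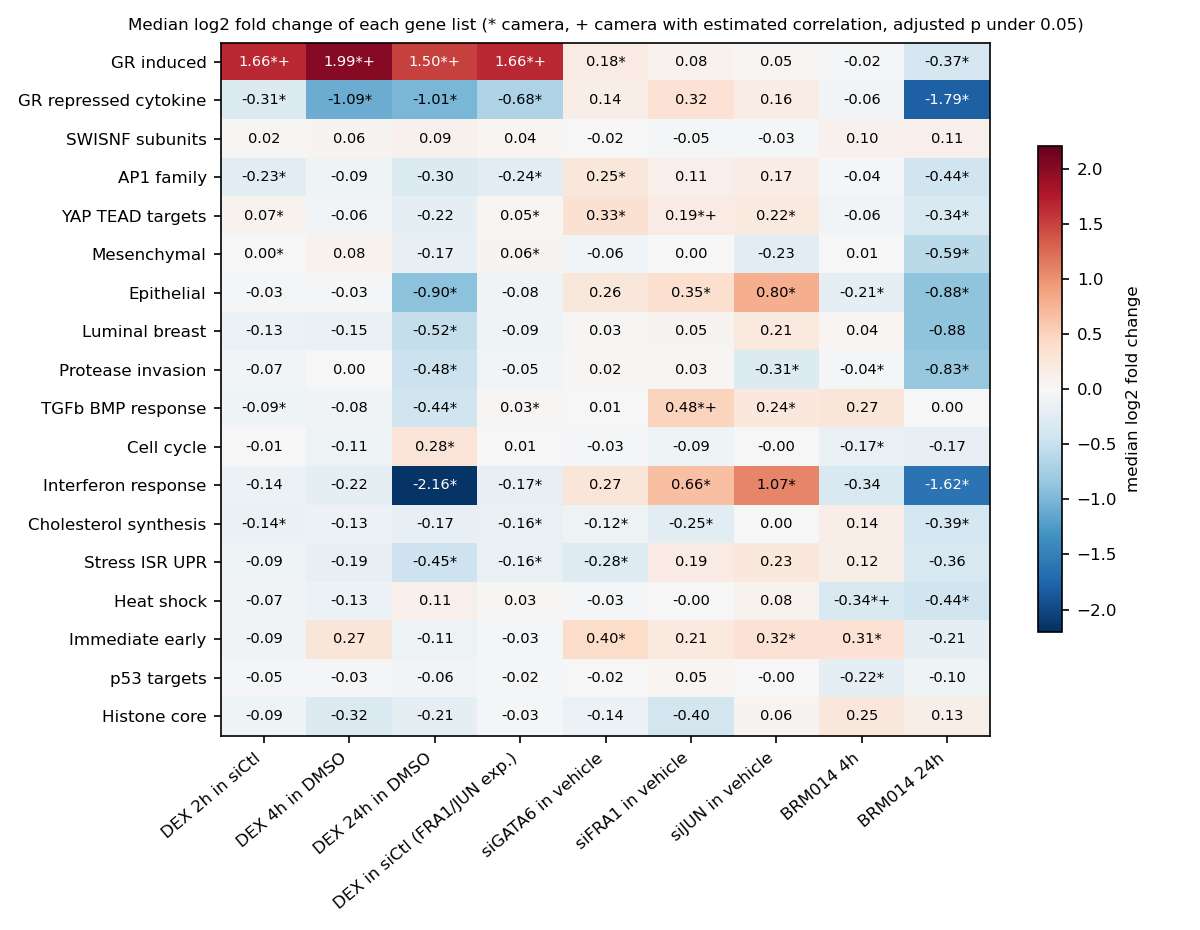
Median log2FC of each gene list (vertical) in the main comparisons (horizontal). An asterisk marks a camera call at the preset correlation, a plus one that held with an estimated correlation. Glucocorticoid-induced genes are high in every DEX column. Interferon genes are lowest at 24 h with DEX (-2.16) and BRM014 (-1.62), against the same DMSO libraries.

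DEX was also given to cells that received BRM014, to ask how far the hormone response needs the ATPases. At 4 h PDK4 rose from 0.0896 ± 0.0441 to 25.6 ± 2.84 CPM (275-fold, adjusted p = 6.33e-13), RASD1 43.7-fold, FKBP5 12.2-fold to 10.2 ± 1.77 CPM, C2CD4A 12.1-fold, SDPR 10.6-fold, ZFAND5 7.50-fold (160.9 ± 21.8 to 1206 ± 90.7 CPM), CDS1 7.40-fold and TXNIP 6.63-fold, and SLC19A2 had a log2FC of 3.00. PCDH18 (5.83-fold lower), the heme oxygenase gene HMOX1 (4.61-fold), IER3, LIF, S1PR1, PDE4B, KSR1, SOWAHD and DUSP4 were among the largest falls. In all, 891 genes were called, 61.95% of them higher, and 493 in total without the replicate-2 libraries. Of the glucocorticoid-induced list 17 rose and 1 fell (21 and 2 adjusted over the list alone; median 1.00, camera adjusted p = 2.74e-48, and adjusted p = 2.31e-06 with an estimated correlation). At 24 h FKBP5 rose 110.5-fold to 128.2 ± 29.1 CPM, PDK4 115-fold, ZBTB16 54.2-fold, KCNK3 26.0-fold, ELN, the elastin gene, 25.0-fold, RRAD 18.3-fold and TFCP2L1 17.2-fold, with SLC2A3 (3.88) and H19 (3.87) beside them. RASGRP3 (8.98-fold lower), GRIN2A (7.68-fold), CDH6 (7.33-fold), SCN9A, NTNG1, IFIT1 (5.09-fold), TRIM2, PADI2, SAMD12 and SYTL2 fell most. In all, 1098 were higher and 903 lower at 24 h (924 and 1264 with library totals alone), with totals of 884 in the fit of these groups alone and 1016 without the replicate-2 libraries. Of the glucocorticoid-induced list 21 of 27 rose (22 and 1 lower adjusted over the list alone; adjusted p = 6.64e-56, and adjusted p = 8.76e-07 with an estimated correlation). Histone genes were called lower, 3 of 15, also adjusted over the list alone (0.0298, and adjusted p = 0.64 with an estimated correlation), but not with the GC trend removed (0.0518) or with replicate number as a block (0.0579).

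The interaction at 4 h tested whether BRM014 changed the DEX response. TSC22D3 reached 412 ± 42.4 CPM with DEX in DMSO and 19.4 ± 1.79 CPM with DEX in BRM014, from 4.63 ± 0.998 and 4.87 ± 0.270 CPM without DEX (interaction -4.49, SE 0.271, adjusted p = 6.28e-09). ELN reached 49.9 ± 11.96 against 2.67 ± 0.172 CPM (-4.52), ADAMTS8 33.8 ± 6.13 against 2.05 ± 0.550 CPM (-4.00), ZBTB16 12.5 ± 0.577 against 1.04 ± 0.363 CPM (adjusted p = 0.00569) and KLF15 10.2 ± 0.208 against 1.33 ± 0.230 CPM (adjusted p = 9.47e-04). A higher DEX ratio in BRM014 was found for C2CD4A (2.99, adjusted p = 2.83e-04), which DEX took from 2.22 to 26.7 CPM with BRM014 and from 11.5 to 17.5 CPM without, and for FGF18 (1.99), SOWAHD (1.68), SLC9A7 (1.63) and NXPH2 (1.59). FOSL1 fell less with DEX under BRM014 (interaction 1.36, adjusted p = 0.00526), from 14.1 to 9.20 CPM against 42.6 to 10.8 CPM in DMSO. Its level with DEX was thus not higher under BRM014, which alone had already lowered it. In all, 333 genes were called, and 82 of them had a higher DEX ratio under BRM014.

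The glucocorticoid-induced list was lower in this interaction, 16 of 27 (21 adjusted over the list alone) with a median of -1.11 (camera adjusted p = 1.45e-67, and adjusted p = 1.62e-07 with an estimated correlation), and the cytokine list was higher on 1 called member, CXCL1 (1.36; 3 higher and 2 lower adjusted over the list alone; 0.00387, and adjusted p = 0.761 with an estimated correlation). Of the 447 genes induced by DEX in control cells of both siRNA experiments, 78.1% had a smaller DEX ratio under BRM014, 130 were called smaller and 5 larger, and the median log2FC with DEX was 1.03 in DMSO and 0.62 in BRM014 (median interaction -0.43, fry adjusted p = 7.78e-08). The 245 repressed genes had a median interaction of 0.23 (fry adjusted p = 0.00138), with 25 called smaller and 4 larger in size. The interaction fell with GC content (rho -0.45 across genes), and the count was 79 without the replicate-2 libraries.

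**Figure D4:**
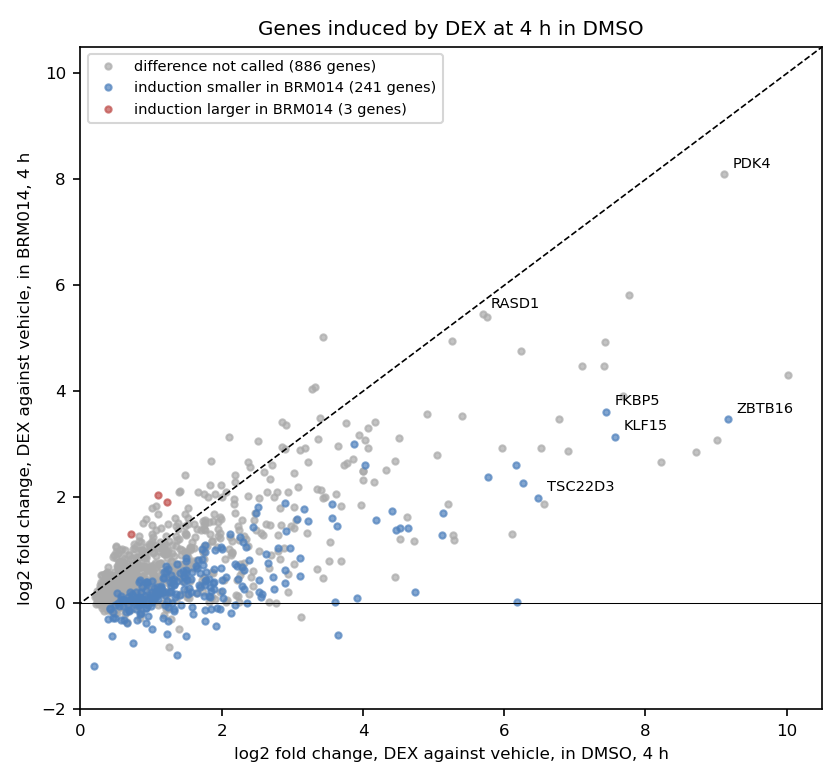
Log2FC with DEX at 4 h in BRM014 (vertical axis) against that in DMSO (horizontal axis) for the 1130 genes that rose in DMSO, with the line of equal response. The interaction was called smaller for 241 of them, such as TSC22D3 and ZBTB16, and larger for 3. The genes were chosen in DMSO libraries that also enter the interaction, so part of this imbalance follows from the choice.

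At 24 h C2CD4A again had the largest gain in DEX ratio under BRM014: DEX took it from 0.785 ± 0.122 to 10.1 ± 2.36 CPM with BRM014 and from 10.6 ± 4.65 to 2.00 ± 0.805 CPM without (interaction 6.03, SE 0.488, adjusted p = 2.14e-07). RGS4 (4.04), the transglutaminase gene TGM2 (3.22), KRT19 (3.11) and PLXNA4 (2.98) followed. ZBTB16 reached 52.1 ± 1.77 CPM with DEX in DMSO and 6.97 ± 1.09 CPM with DEX in BRM014 (-4.46, SE 0.855, adjusted p = 0.00233). LBH reached 19.6 ± 4.91 against 0.340 ± 0.0558 CPM, CPAMD8 9.65 ± 2.60 against 0.354 ± 0.263 CPM, the cannabinoid receptor gene CNR1 5.72 ± 1.57 against 0.504 ± 0.193 CPM, and ABLIM3, with DEX in BRM014, 1.52 ± 0.799 CPM (adjusted p = 0.0177). In all, 952 genes were called, and 404 of them had a lower DEX ratio under BRM014. The total was 1507 with GC trends removed, 1498 with replicate number as a block and 533 with these groups alone. Without the replicate-2 libraries, with fewer samples, 169 were higher and 86 lower.

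Of 27 glucocorticoid-induced genes 11 were lower in this interaction and 1 higher (13 and 2 adjusted over the list alone; median -0.49, camera adjusted p = 1.05e-12, and adjusted p = 0.0052 with an estimated correlation), TFCP2L1 (-4.05), TSC22D3 (-3.81) and FKBP5 (-3.37) beside ZBTB16. Of 21 YAP/TEAD readout genes 7 were higher, also adjusted over the list alone, such as CTGF (1.79) and TGFB2 (1.11) (adjusted p = 6.14e-04, and adjusted p = 0.0482 with an estimated correlation). TGF-beta and BMP genes were higher in 3 of 15 (4 adjusted over the list alone), BMP4 (1.55), ID3 (0.73) and SMAD7 (0.57) (0.00571, and adjusted p = 0.0482 with an estimated correlation). Interferon genes had a median of 1.19 with 2 of 30 higher (3 adjusted over the list alone), IRF7 (1.51) and IRF1 (0.80) (2.76e-08, and adjusted p = 0.351 with an estimated correlation). The cytokine list had 3 of 11 higher (7 adjusted over the list alone), CXCL1 (2.09) first (3.57e-08, and adjusted p = 0.0735 with an estimated correlation). The 447 DEX-induced genes had a median interaction of -0.05 (fry adjusted p = 0.24), with 74 called smaller and 46 larger. The 245 repressed ones had a median of 0.28 (fry adjusted p = 4.37e-04), with 37 called smaller in size and 7 larger.

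The effects at 24 h and 4 h were also tested against each other. For BRM014, 420 genes had a higher and 953 a lower effect at 24 h (969 and 722 with library totals alone, which shifted the median of all genes by 0.137), and 113 were higher and 432 lower without the replicate-2 libraries. For DEX, 380 were higher and 914 lower (702 and 827 with library totals alone), and 381 in total without those libraries.

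DEX was compared with vehicle again in siCtl cells of the AP-1 experiment. PDK4 rose from 1.09 ± 0.426 to 216.2 ± 32.4 CPM (195.9-fold, SE 0.234 on the log2 scale, adjusted p = 8.92e-13), TSC22D3 71.3-fold, F3 22.9-fold, FKBP5 17.3-fold, SLC19A2 13.2-fold and the forkhead factor gene FOXO1 7.45-fold, with RASD1 (4.94), SDPR (3.44), KLF9 (3.37) and OSR1 (log2FC 3.25) among the 10. ZBTB16 went from 1 to 117 counts over the group (ratio 128, interval 22.5 to 5100). IER3 (8.93-fold lower, adjusted p = 7.44e-11), SOWAHD, ELF3 (6.10-fold), TNFSF9, PCDH18, CXCL8 (5.07-fold), LIF (4.63-fold), GDF15 (4.12-fold) and PDE4B were among the largest falls, and FOSL1 fell by 1.52 (adjusted p = 3.38e-05). In all, 472 genes were higher and 280 lower (383 and 371 with library totals alone), and 798 and 532 with the replicate number as a block.

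The glucocorticoid-induced list rose in 20 and fell in 1 of 27 (22 and 1 adjusted over the list alone; median 1.66, camera adjusted p = 8.73e-121, and adjusted p = 5.30e-07 with an estimated correlation). The cytokine list fell in 4 of 11 (5 adjusted over the list alone), CXCL8, LIF, CCL2 (-1.47) and CXCL2 (-0.69) (adjusted p = 1.03e-06, and adjusted p = 0.144 with an estimated correlation). AP-1 genes fell in 2 of 16 (3 adjusted over the list alone), FOSL1 and ATF3 (0.00726, and adjusted p = 0.379 with an estimated correlation), and cholesterol genes in 5 of 24 (8 adjusted over the list alone), HMGCS1 (-0.66) among them (9.75e-05, and adjusted p = 0.218 with an estimated correlation). Mesenchymal genes rose in 5 of 24, also adjusted over the list alone, ZEB2 (1.82) and TWIST1 (1.29) first (2.97e-04, and adjusted p = 0.218 with an estimated correlation). For TGF-beta and BMP genes the test was called lower (0.00726, and adjusted p = 0.193 with an estimated correlation) with a mean of -0.34, but the median was 0.03, and -0.03 with library totals alone. YAP/TEAD genes were called higher (0.00726, and adjusted p = 0.0592 with an estimated correlation) with a median of 0.05, and -0.01 with library totals alone. Interferon genes had 1 of 31 lower, IRF1 (-1.54), also adjusted over the list alone (0.039, and adjusted p = 0.837 with an estimated correlation), and were not called with library totals alone (0.135) or without siCtl vehicle replicate 1 or 3, and their median turned to 0.0700 without siCtl DEX replicate 2. Stress genes had 2 of 18 lower and 1 higher, also adjusted over the list alone (0.0322, and adjusted p = 0.821 with an estimated correlation).

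The DEX responses of control cells in the separate experiments were set side by side. Across genes, which are not independent replicates, the log2FC at 2 h correlated with that at 4 h (Pearson 0.78) and with that of the AP-1 experiment (0.78), and the 4 h one with the AP-1 one (0.71). Of genes called in both members of a pair, 1046 of 1054, 692 of 692 and 533 of 535 moved the same way, where independent lists would share 277.8, 121.9 and 95.1 calls in either direction. In all 3 experiments 350 genes rose and 161 fell.

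Loss of FRA1 was read from siFRA1 against siCtl with vehicle. DHRS2 rose from 1.78 ± 0.703 to 18.9 ± 9.86 CPM (log2FC 3.41, SE 0.632, adjusted p = 0.00383) and SULF1, which encodes an extracellular sulfatase, 4.82-fold. NFE2L3 (2.04), SLITRK6 (2.03), PADI2 (1.90), TRAF1 (1.78), ACHE (1.77), HR (1.68), GBP4 (1.63) and APOL1 (1.61) also rose. BAALC fell 4.19-fold (36.7 ± 2.61 to 8.71 ± 2.71 CPM), and ATP6V1G1, a proton pump subunit gene, from 169.2 ± 0.762 to 55.3 ± 5.03 CPM (adjusted p = 1.04e-10). IGFN1 (-1.69), NDP (-1.63), BARX2 (-1.55), NPTX1 (-1.54), MYH15 (-1.51), TMEM184B (-1.41) and the T-box gene EOMES (-1.35) were lower too. In all, 756 genes were higher and 721 lower, and 1712 and 1645 with the replicate block. The total was 910 and 826 without siCtl replicate 1 or 2, and 802 without siFRA1 replicate 1.

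TGF-beta and BMP genes rose in 7 of 15 (9 adjusted over the list alone), INHBA (1.56), SKIL (0.80) and ID4 (0.69) among them (median 0.48, camera adjusted p = 1.63e-10, and adjusted p = 0.00445 with an estimated correlation). YAP/TEAD genes rose in 7 and fell in 2 of 20 (10 and 3 adjusted over the list alone), NUAK2 (1.04) and CTGF (0.90) among them (adjusted p = 0.00478, and adjusted p = 0.0346 with an estimated correlation). Of 13 epithelial genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with CLDN3 (2.88), KRT18 (2.14) and KRT8 (1.87) higher and KRT19 (-1.26) lower (0.00955, and adjusted p = 0.123 with an estimated correlation). Interferon genes rose in 3 of 31 (4 adjusted over the list alone), CXCL10 (2.12), IFIH1 (1.07) and MX2 (0.52) (2.03e-08, and adjusted p = 0.482 with an estimated correlation). Cholesterol genes fell in 8 of 24 (12 adjusted over the list alone), MVD (-0.51) first (6.62e-06, and adjusted p = 0.159 with an estimated correlation).

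In siJUN against siCtl with vehicle, interferon-related genes were among the largest rises. GBP4, an interferon-induced GTPase gene, rose from 11.7 ± 3.79 to 77.9 ± 30.1 CPM (log2FC 2.75, SE 0.396, adjusted p = 0.00123), followed by BATF2 (2.66), ETV7 (2.32), SULF1 (2.07), RGS5 (2.06), the necroptosis effector gene MLKL (2.01), IFIT2 (2.01), TRIM22 (2.00), GBP5 (1.98) and RSAD2 (84.9 ± 32.9 to 332.1 ± 84.4 CPM). COL13A1 (2.92-fold lower), CDH18, GEM (2.69-fold), SHANK2, RSPO2 (114.4 ± 3.88 to 43.8 ± 3.98 CPM), NPTX1, BAALC (2.51-fold), the hyaluronan synthase gene HAS3 (263.4 ± 12.5 to 108.9 ± 13.2 CPM) and KCNJ12 fell. In all, 503 genes were higher and 429 lower, and 1236 and 1314 with the replicate block. The total was 621, 597 and 605 without siCtl replicate 1, 2 or 3, and 444 without siJUN replicate 1.

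Of 31 interferon response genes 16 rose (28 adjusted over the list alone), CXCL10 (3.55) and IFIT3 (1.70) beside those above (median 1.07, camera adjusted p = 5.86e-25, and adjusted p = 0.164 with an estimated correlation). Epithelial genes rose in 6 of 13 (6, with 3 lower, adjusted over the list alone), KRT18 (1.67), KRT8 (1.34) and CDH1 (1.26) first (adjusted p = 0.0187, and adjusted p = 0.164 with an estimated correlation). Protease genes had 2 of 20 lower and 1 higher (7 and 1 adjusted over the list alone), MMP1 (-1.04) and CTSB (-0.60) against TIMP3 (1.03) (1.63e-04, and adjusted p = 0.164 with an estimated correlation). YAP/TEAD genes rose in 6 of 20 (9, with 3 lower, adjusted over the list alone; 0.00473, and adjusted p = 0.0585 with an estimated correlation), TGF-beta and BMP genes in 3 of 15 (5, with 1 lower, adjusted over the list alone; 0.0115, and adjusted p = 0.164 with an estimated correlation) and immediate early genes in 2 of 20, KLF2 (1.56) and KLF4 (0.72) (3 adjusted over the list alone; 0.0115, and adjusted p = 0.529 with an estimated correlation).

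siJUN was then compared with siFRA1 directly. HBEGF, a growth factor gene, was 5.08-fold lower in siJUN (6.13 ± 0.605 against 31.1 ± 3.03 CPM, adjusted p = 5.39e-09), as were INHBB (-2.04), PRSS35 (-1.97), DHRS2 (-1.97) and WNT2B (-1.75). FOSL1 (2.00), FGF1 (1.86), EGR3 (1.83), EPHA7 (1.63) and the carboxypeptidase M gene (1.59) were higher. Cholesterol genes were higher in 5 of 24 (13 adjusted over the list alone; camera adjusted p = 7.14e-07, and adjusted p = 0.117 with an estimated correlation), protease genes lower in 4 of 20, ADAMTS1 (-0.97) among them (6 adjusted over the list alone; 1.83e-05, and adjusted p = 0.0892 with an estimated correlation), and TGF-beta and BMP genes lower in 3 of 15 (5 adjusted over the list alone; 5.36e-05, and adjusted p = 0.0759 with an estimated correlation). Interferon genes had 1 of 31 higher, CXCL10 (0 adjusted over the list alone; 4.95e-04, and adjusted p = 0.922 with an estimated correlation). Histone genes had 1 of 15 higher, HIST1H2BD, also adjusted over the list alone (0.0116, and adjusted p = 0.0759 with an estimated correlation), and were not called with the block (0.0683). In all, 513 genes were higher and 644 lower in siJUN, and 1316 and 1486 with the block. The total was 684 with these groups alone, 646 without siFRA1 replicate 1, and 641 and 639 without siJUN replicate 1 or 2.

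The siFRA1 and siJUN effects shared 204 higher genes (27.8 expected of independent lists) and 155 lower ones (22.7 expected), and 14 moved in opposite directions. Their log2FC correlated at 0.594 across genes with a covariance of 0.0923, where unchanged groups simulated against the same siCtl libraries gave 0.495 and 0.0232. The 3 control libraries could not be split into parts with 2 libraries each, so part of the excess may come from the shared controls. Between siFRA1 with vehicle and siJUN with DEX, which share no library, the correlation was 0.421 and the covariance 0.0625.

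Whether siFRA1 or siJUN alters the DEX response was tested as before. With edgeR 0 genes were called in either interaction, with 302 (siFRA1) and 378 (siJUN) at an unadjusted p under 0.05. DESeq2 called 2 and 0, and the replicate block 6 in each. The 649 genes induced by DEX in control cells of both other experiments had median interactions of -0.06 with siFRA1 (fry adjusted p = 0.24, and 0.00302 with the block) and -0.03 with siJUN (fry adjusted p = 0.549). The 379 repressed ones had medians of 0.04 and 0.03 (fry adjusted p = 0.436 for each). No list was called in either interaction, but with the block YAP/TEAD and interferon genes were called for siFRA1 (adjusted p = 0.0208 for each), with medians of -0.06 and 0.15 in that fit. Neither held with an estimated correlation (adjusted p = 0.176 and 0.854).

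BRM014 and siRNA calls were compared by Fisher's exact test adjusted over 24 overlaps, which takes genes as independent, though they are not. Genes lower with BRM014 at 4 h included 70 that were lower in siJUN (18.5 expected, odds ratio 4.79, adjusted p = 6.86e-22) and 43 that were higher (20.98 expected, 2.24). They included 169 that were higher in siGATA6 (71.0 expected, 3.15, adjusted p = 5.68e-28) and 72 that were lower (68.8 expected, 1.06, adjusted p = 0.647). With siFRA1, 78 were higher (32.2 expected, 2.83) and 54 lower (1.89, adjusted p = 1.24e-04). Genes lower with BRM014 at 24 h included 215 lower in siJUN (74.0 expected, 5.21, adjusted p = 1.47e-55) and 157 higher (84.1 expected, 2.37, adjusted p = 7.69e-16). They included 451 lower (276.7 expected, 2.08, adjusted p = 6.85e-30) and 456 higher in siGATA6 (285.8 expected, 2.01, adjusted p = 5.14e-28), and 194 lower (1.84) and 231 higher in siFRA1 (2.27), with no common direction. Those higher at 24 h included 22 lower in siJUN (63.3 expected, 0.305).

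Leukocyte marker genes were not tested as a list, since of 12 only 2, 3 and 2 passed the count filter in the GATA6, BRM014 and AP-1 experiments.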

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

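The trades of 1 library in each pair of groups, the tests with GC trends removed, the siRNA duplex test, the spread and pairing of the relabelings and the test of spread within replicate numbers were chosen only after the results were seen.

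The effect of BRM014 differed between 24 h and 4 h for 1373 genes, tested as an interaction. FGFR3 rose at 24 h (4.54 to 37.4 CPM) more than at 4 h (4.93 to 6.55 CPM; difference 2.62, SE 0.219, adjusted p = 1.30e-07), as did C2CD4C (2.45), KIF1A (2.39), HR (2.18) and CHD5 (2.06). CPA4 was at 1.81 CPM with BRM014 and 37.5 CPM with DMSO at 24 h, and at 45.7 and 38.9 CPM at 4 h (difference -4.59), and KRT19 (-4.39), KCNK3 (-4.35) and GBP2 (-4.27) were also lower. The list medians of the difference were -1.74 for cytokine genes (camera adjusted p = 6.68e-12, and adjusted p = 0.0356 with an estimated correlation) and -0.54 for mesenchymal genes (1.45e-09, and adjusted p = 0.0194 with an estimated correlation). The other called lists did not hold with an estimated correlation (adjusted p from 0.0689 to 0.341): medians were -1.30 for interferon, -0.72 for epithelial, -0.53 for immediate early, -0.50 for cholesterol, -0.49 for stress, -0.45 for protease, -0.42 for AP-1, -0.25 for YAP/TEAD, -0.23 for glucocorticoid-induced and -0.12 for TGF-beta and BMP genes, the last being 0.02 with library totals alone.

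The effect of DEX differed between 24 h and 4 h for 1294 genes. The difference was 4.28 for LBH, 4.08 for ABLIM3, 3.85 for H19, 3.77 for SCNN1A and 3.37 for CD248, and -4.71 for KCNV1, -4.14 for KLF15, -4.13 for SEMA5B, -4.10 for RRAD and -3.88 for IDO1. Called lists had medians of -1.82 for interferon, -0.90 for epithelial, -0.67 for luminal, -0.46 for mesenchymal, -0.41 for protease, -0.36 for stress, -0.19 for YAP/TEAD, 0.30 for cell cycle and 0.10 for SWI/SNF subunit genes, and none of these held with an estimated correlation (adjusted p from 0.15 to 0.446).

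Fold changes with BRM014 at 4 h rose with GC content, and the GC slope varied among libraries. With each library's GC trend removed, 1153 of the 1262 genes were still called in the same direction, and the DEX-induced set kept a smaller response in BRM014 at 4 h (median interaction -0.45, fry adjusted p = 1.00e-07), which argues against a GC trend as the whole cause of either. At 24 h the interaction is less certain: trading DMSO replicate 3, BRM014 replicate 2, DEX replicate 2 and DEX with BRM014 replicate 3, whose GC slopes were -1.44, 2.52, 4.4 and -1.22, called 1724 genes against the real 952 (2 of 40 labelings as large, the real one included). Chance was not excluded for the counts of the interaction at either time. An effect of ATPase inhibition on the hormone response may account for the 4 h result, as a hypothesis.

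The siGATA6 interaction with DEX also rose with GC content. Of the 90 higher and 162 lower genes called under the replicate block, 163 were still called in the same direction with the GC trend also removed, which argues against GC as the whole cause. Whether chance gives a count of 47 stays open: 4 of 100 drawn relabelings, the real one included, gave as many, but the other 99 mix groups, which raised the coefficient of variation from 5.57% to between 8.17% and 11%, so calls become fewer in any case. The 3 others as large, of which the highest gave 377, left 1 pair of groups unmixed, so that an siRNA effect stays in the contrast by construction, and 0 of the 15 that kept each replicate number once in every group gave as many. The higher RN7SK and RNA45S5 in the siGATA6 libraries stays open as untested.

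Interferon genes were higher after siJUN in each replicate number, with medians of 1.03, 1.55 and 0.80, while siCtl libraries differed from each other by up to 0.851. The lowest of these, 0.80, had been set in advance against that spread and did not exceed it, so that test cannot decide. The differences, tested again after they were seen, had a mean of 1.13 and an SD of 0.385, so spread within pairs stays open. With 3 pairs no exact two-sided sign-flip p is under 0.25. A response to siRNA duplexes, or a low level in the siCtl libraries, stays open, since the list was also higher with siFRA1 in each number, with medians of 0.67, 0.81 and 0.69 (camera adjusted p = 2.03e-08, and adjusted p = 0.482 with an estimated correlation), and after siGATA6 it had a median of 0.27 with adjusted p = 0.358, but 2.39e-04 with the replicate block (adjusted p = 0.606 with an estimated correlation). An effect of lower JUN itself may be the source, as a hypothesis.

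For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05: in each of them 1 split, the real one, gave a count as large and the highest other was 0, against real counts of 2216 and 2215 for DEX at 2 h in siCtl and siGATA6, 3291 for siGATA6, 1262 and 4589 for BRM014, 1825 and 3717 for DEX in DMSO, 891 and 2001 for DEX in BRM014, 752 for DEX in the AP-1 experiment, 1477 for siFRA1, 932 for siJUN and 1157 for siJUN against siFRA1. In the BRM014 experiment the drawn relabelings, the real one counted, did not exclude chance: 4 of 50 for the interaction at 4 h (real 333, highest other 949), 8 of 50 at 24 h (952, 3508), 7 of 50 for BRM014 over time (1373, 2106) and 5 of 50 for DEX over time (1294, 2083). For the interactions the highest other is several times the real count, which points to a structure of the samples. Of the others as large, 3 of 3 at 4 h, 6 of 7 at 24 h, and 6 of 6 and 4 of 4 over time left 1 pair of groups unmixed. The effect within that pair then stays in the contrast by construction, and no other structure was tested. In the trades, the real labels counted, 1 of 40 gave as many for the interaction at 4 h and for both effects over time, and 1 of 82 for siGATA6 by DEX, the highest other being 0. Trades mix treated and untreated libraries in every group, which raised the coefficient of variation from 18.8% to between 20.2% and 25.4% in the BRM014 experiment and from 5.57% to between 10.3% and 11% in the GATA6 experiment, so calls become fewer in any case and the trades decide nothing about chance. The drawn relabelings also raised it, in 49 of 49 for both interactions and in 45 of 49 for both effects over time. For the siFRA1 and siJUN interactions, with 0 genes called, 100 of 100 relabelings gave as many, the highest other 827 and 2.6e+02.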

How the results depend on the processing

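The removal of GC trends, alone or with the block, the estimated correlation with the block and the omission of the replicate-2 libraries were chosen after seeing the data.

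Counts of called genes stayed within 1.5 times in all 20 comparisons with library totals, RLE factors or a mean CPM of at least 1. DESeq2 moved the siGATA6 by DEX interaction to 88 and siFRA1 by DEX to 2, and no low-count filter moved the former to 95. The replicate block gave 2.5e+02 for siGATA6 by DEX (90 higher, 162 lower), 1498 for BRM014 by DEX at 24 h, 1945 for DEX over time, 1330 for DEX in the AP-1 experiment, 3357 for siFRA1, 2550 for siJUN, 2802 for siJUN against siFRA1 and 6 for each of their interactions with DEX. It also moved the DEX-induced set to -0.0461 with siGATA6 (adjusted p = 0.0462) and -0.0593 with siFRA1 (0.00302), and no other set call. In the BRM014 experiment 63 of 84 same-number pairs correlated above 0.1 and 21 of 24 libraries correlated best with their own number, and outside DEX in DMSO and DEX at 24 h in BRM014 the numbers were not taken as pairs. There the block also called interferon genes lower with BRM014 at 4 h (median -0.30, adjusted p = 2.30e-05, and adjusted p = 0.282 with an estimated correlation). The groups of the contrast alone gave 2868 and 1788 for DEX in DMSO at 4 and 24 h, 884 for DEX in BRM014 at 24 h, 533 for BRM014 by DEX at 24 h and 684 for siJUN against siFRA1. GC removal gave 1507 for BRM014 by DEX at 24 h. GC removal with the block gave 181 for siGATA6 by DEX, 2377 for BRM014 at 4 h, 2897 for DEX at 4 h, 1644 and 3501 for DEX in BRM014, 588 and 2330 for BRM014 by DEX, 2817 and 2820 for the effects over time, 1418 for DEX in the AP-1 experiment, 3570, 2714 and 2850 for siFRA1, siJUN and their difference, 11 and 10 for their interactions, and -0.0561 for the DEX-induced set with siFRA1 (0.00631). Without the replicate-2 libraries, with fewer samples, BRM014 gave 383 and 3036, DEX 1065 and 1945, DEX in BRM014 493 and 1016, BRM014 by DEX 79 and 2.6e+02 (169 higher, 86 lower), and the effects over time 5.5e+02 (113 higher, 432 lower) and 381. Where not stated otherwise the cause was not tested.

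Camera in place of fry called the DEX-induced set with siGATA6 (-0.0513, adjusted p = 7.68e-04), BRM014 at 24 h (-0.0490, 0.0373) and siFRA1 (-0.0578, 3.92e-05) and the repressed set with siGATA6 (0.0334, 0.00513) and siFRA1 (0.04, 0.0373). The set of genes changed at least 2-fold gave -0.197 with BRM014 at 24 h (0.0267). Overlaps of genes changed at least 2-fold, which are few by construction, had odds ratios for higher with BRM014 at 4 h of 2.37 with higher in siGATA6, reversed (adjusted p = 0.495), 2.61 with higher in siFRA1 (0.278) and 0 with lower in siFRA1 or siJUN (1 each). At 24 h they were 2.73 with higher in siGATA6, reversed (0.0355), 1.34 with higher in siJUN, reversed (0.536), and 0 with lower in siFRA1 (0.536) or siJUN (0.73). DESeq2 calls gave 0.795 at 4 h for higher with higher in siGATA6 (0.126) and 0.826 at 24 h for higher with lower in siGATA6 (0.0293). Of 119 list calls, 16 held with an estimated correlation and 35 with that and the block.

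Leaving out 1 library gave 1758 to 1968 for DEX at 2 h, 1788 to 1990 in siGATA6, 2475 to 2980 for siGATA6, 30 to 56 for its interaction, 751 to 1170 and 3822 to 4270 for BRM014, 1401 to 1702 and 2848 to 3701 for DEX in DMSO, 652 to 785 and 1460 to 1951 for DEX in BRM014, 2.6e+02 to 321 and 699 to 1017 for BRM014 by DEX, 995 to 1308 and 891 to 1275 over time, 597 to 637 for DEX in the AP-1 experiment, 802 to 1182 for siFRA1, 444 to 1321 for siJUN, 639 to 1330 for their difference and 0 for both interactions. The DEX-induced set with siGATA6 ranged from -0.0697 to -0.0205 and was called without siGATA6 vehicle replicate 3 (0.041). Interferon genes with DEX in the AP-1 experiment ranged from -0.41 without siCtl vehicle replicate 2 to 0.0700 without siCtl DEX replicate 2, which reversed the direction.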

Other observations

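The tests below were chosen before the results they measure were seen.

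DEX also moved gene groups in cells with BRM014. At 4 h immediate early genes rose in 7 and fell in 3 of 20 (8 and 3 adjusted over the list alone), EGR3 (2.66), ARC (2.11) and ZFP36 (2.06) first (camera adjusted p = 0.00279, and adjusted p = 0.485 with an estimated correlation). Cytokine genes fell in 3 of 11 (6 adjusted over the list alone), CCL2 by 3.01 (1.81e-04, and adjusted p = 0.485 with an estimated correlation). At 24 h interferon genes fell in 5 of 30 (16 adjusted over the list alone), IFIT1, MX1 (-2.02) and OASL (-1.87) among them (3.27e-06, and adjusted p = 0.64 with an estimated correlation), and immediate early genes rose in 5 of 20 (6 adjusted over the list alone), EGR3 (2.33) first (0.00225, and adjusted p = 0.64 with an estimated correlation).

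DEX-induced genes with a smaller induction in BRM014 at 4 h were hypothesised to need GATA6, FRA1 or JUN. Overlaps with genes lower after each siRNA without DEX were tested by Fisher's exact test. The odds ratios were 1.08 for GATA6 (interval 0.685 to 1.66, adjusted p = 0.992), 0.957 for FRA1 (0.512 to 1.7, adjusted p = 1) and 1.39 for JUN (0.789 to 2.38, adjusted p = 0.412). An adjusted p over the threshold had been set in advance as evidence against each, but the intervals span a ratio of 1 and leave moderate overlaps open, so none is excluded. An overlap with smaller induction at 24 h, as predicted, had an odds ratio of 4.22 (2.79 to 6.42, adjusted p = 4.69e-12). It held for 48.1% of 162 genes against 18% of 417. Both times share 1 experiment and fit, so this cannot show that the reduction lasts.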
